A study of Drosophila melanogaster with 2 samples.

How the data were processed

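The study measured, by ChIP-seq, where an NFAT-eGFP fusion protein was bound in whole Drosophila melanogaster embryos aged 0 to 24 h. Chromatin was sheared by sonication to a size range of 200 to 800 and precipitated with an anti-GFP antibody, per the labels. The 2 samples are biological replicates 1 and 2 of 1 group, per the labels. A possible control experiment is named in the labels, and its files are not used here.

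The data used were 8 peak lists on the dm6 assembly, per the labels and the deposited file descriptions: for each replicate and for both replicates together, a list of all ranked peaks and a shorter list thresholded by the irreproducible discovery rate (IDR), the rate expected for peaks whose rank does not repeat between replicates. The series-level thresholded lists come as a larger and a conservative version, per the deposited file descriptions. Per replicate lists were derived from that replicate alone, so they can be compared by overlap. The aligner, the peak caller and their versions are not given in the sources used here. The lists follow the narrowPeak column order. The seventh column is a signal value per peak made by the authors' caller, on a scale that is not given in the sources used here, so signal was used only to rank and describe peaks within a list. The ninth column is the −log10 of a q-value in the deposited lists, and column 12 of the deposited ranked lists holds the −log10 of a global IDR. In the deposited ranked series-level list, columns 15 and 19 hold the signals of the matched peaks in the compared lists, used here only as a score to find peaks whose own signal was lower than both. The tenth deposited column gives the summit offset. The deposited thresholded lists stop at a global IDR of 0.01. Some ranked peaks past that limit do not appear in the thresholded lists (216 for the larger one), and these were left out of the main results.

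Peaks on 2L, 2R, 3L, 3R, 4, X and Y were used, and 25 peaks of the larger list on other contigs were left out. All peak ends lay within the arm lengths of the Release 6 genome sequence used for motif searches. TSSs, genes, exons and UTRs came from Ensembl release 115 (BDGP 6.54). Gene symbols fixed beforehand were matched to the annotation. Of these, 8 were matched through listed synonyms and 6 had no match and were not used. Replicate overlap counted peaks that shared at least 1 bp, against 10000 random placements of the same peaks within each arm. Promoter summits lay within 500 bp of a protein-coding TSS. Each summit was given the first class that applied of promoter, 5' UTR, coding exon, 3' UTR, other exon, intron and intergenic, and each class was tested against 10000 placements. Motifs were searched on both strands in 101 bp centred on the summit and in 101 bp centred 400 bp to the left or right, alternating by rank. Pairs of windows were compared by an exact sign test for 25 listed motifs and for all 2080 hexamers. The 22 gene lists were compared with all other protein-coding genes by Fisher's exact test, two-sided. Adjusted p-values are Benjamini-Hochberg values within each family (7 classes, 25 motifs, 2080 hexamers, 22 lists, 10 trends with strength), with a threshold of 0.05. Spearman correlations used 100000 permutations, and 10000 for all ranked pairs and for ranks by q-value.

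Genes were named by rules fixed before the data were examined: the protein-coding gene with the TSS nearest to each of the 25 strongest summits of the larger list, up to 4 members of each gene list with the strongest peak within 1000 bp of a TSS, and NFAT. With 1 group, no test between conditions was possible, and p-values compare peaks with sequence or genes within this pair of samples. The list results count genes, many of which share a promoter region with a neighbour and so share a peak.

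The steps were tested on simulated data. With 30% of 4899 random summits moved into promoters, 38.4% were found there against 38.2% expected. With DRE planted in 3% of 4899 summit windows, the planted share was recovered, no other listed motif was called, and 2 hexamers were called. With random summits, none of 25 motifs and none of 2080 hexamers was called. These summits were placed anywhere on the arms, so the simulation does not cover the difference in base composition between real summits and their flanks. With random gene hits none of 22 lists was called, and with ribosomal protein genes hit more often that list alone was called.

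Alternatives fixed beforehand numbered 44, and 15 more were chosen after the data were seen. They cover the conservative list, each replicate alone, the stronger peaks, other windows, overlaps, backgrounds and sets of genes. Analyses used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.

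Tracks of fold change and p-value over a control, named in the deposited descriptions, and the alignments are not used here.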

Results

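NFAT, a Rel-domain transcription factor and the fly member of the NFAT family, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole Drosophila melanogaster embryos collected 0 to 24 h after laying. The flies carried an NFAT fusion to enhanced green fluorescent protein (eGFP), and chromatin was recovered with an antibody against GFP. The 2 samples were biological replicates of 1 group, so the design gives no treated and untreated condition. The comparisons it allows are between the replicates, between peaks and the rest of the genome, and between stronger and weaker peaks. Replicate 1 had 2263 thresholded peaks and replicate 2 had 4000. Over both replicates, the larger series-level list held 4924 peaks and the conservative one 3926. Of the larger list, 4899 peaks lay on the chromosome arms and enter the results below. The lists give no read totals, so sequencing depth is unknown, and intervals on shares of peaks (Wilson, 95%) cover counting error only. No control immunoprecipitation was analysed here.

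The replicates found largely the same strong sites. All 25 of the strongest peaks of the larger series-level list overlapped thresholded peaks in both replicates, among them those at CG14100, Ugalt (a UDP-galactose transporter), mRpL41 (a mitochondrial ribosomal protein) and ph-p (the Polycomb group gene polyhomeotic proximal). That list was made from both replicates together, so this overlap is not an independent sign of agreement. In replicate 1, 1957 of 2236 peaks (87.5%, interval 86.1 to 88.8%) overlapped a replicate 2 peak by at least 1 bp. In the other direction 1965 of 3994 replicate 2 peaks did (49.2%, 47.6 to 50.7%). Random placement of the same peaks gave 1.47% and 0.823% (one-sided permutation test, p = 0.0001 in each direction, the smallest that 10000 placements can give). Replicate 2 peaks shared with replicate 1 had a median signal of 95.4 and the others 52.9, and 80.6% of the 2029 unshared ones overlapped a lower-ranked peak of replicate 1, against 39.4% under random placement of these peaks (one-sided permutation test, chosen after seeing the data, p = 0.0001, the smallest possible). At 1940 mutually matched peaks, signal agreed in rank across peaks with a Spearman rho of 0.798 and a Pearson r of 0.848 on the log10 scale (permutation p = 1e-05 for each, the smallest possible). These coefficients are across peaks of 1 pair of samples, and peaks are not independent replicates. Summits of matched peaks lay a median of 14 bp apart. With the strongest 1118 peaks of each replicate, 78.1% were shared in either direction, so the value for replicate 2 moved by over 1.5 times with list length. Over all 68035 matched ranked peaks rho was 0.371.

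**Figure D1:**
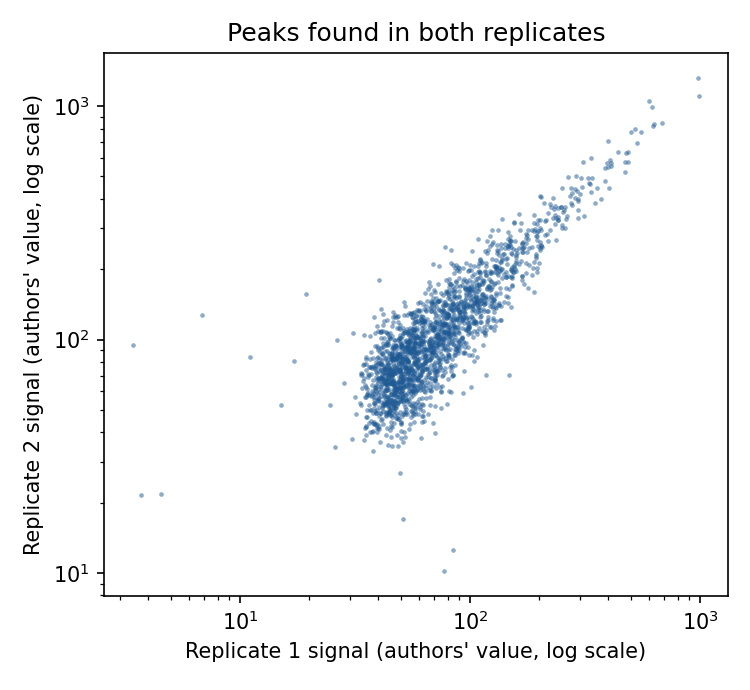
Signal of the 1940 peaks matched between the replicates, replicate 1 on the horizontal and replicate 2 on the vertical axis, both the authors' values on log scales. Each point is a peak, and the points rise together, with a Spearman rho of 0.798.

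Most NFAT-eGFP peaks lay at promoters. The strongest peak, with a signal of 2300, had its summit 97 bp from the transcription start site (TSS) of CG14100 (3L, peak 19590474 to 19590788, dm6). The next lay 32 bp from the TSS of Ugalt (X, 2703724 to 2704044, signal 2086). The peak at mRpL41 (2R, 15217597 to 15217922, signal 1613) was 117 bp from a TSS, and the peak at eIF6 (2R, 23850272 to 23850545, signal 1522), a ribosome biogenesis and translation initiation factor, was 116 bp from one. Of the 25 strongest peaks, 16 were promoter peaks, within 500 bp of a protein-coding TSS. The others among these were CG7601, Tcs5, CenG1A, Art3, CG5611, PNPase, CG1888, moody, Atat, mRpL23, CG13390 and Elp5, with signals from 1456 at CG7601 down to 927 at Elp5 and summits between 50 bp (Elp5) and 225 bp (CG1888) from a TSS. A further 8 summits were intronic, nearest to the TSSs of CG11050, ph-p, NFAT itself, CG9663, CG32772, Adf1, CG3726 and Tlk. The strongest of them lay 1041 bp from the TSS of CG11050 (2L, 6612529 to 6612958, signal 1669). The summit at ph-p (X, 2137208 to 2137496, signal 1319) lay 502 bp from the nearest TSS. The remaining summit, near sp3 (3R, 21520243 to 21520479, signal 980), was intergenic, 572 bp from the TSS.

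Across the larger list, 2753 of 4899 summits (56.2%, interval 54.8 to 57.6%) were within 500 bp of a protein-coding TSS. Random placement on the same arms gave 11.5%, a 4.89-fold difference (two-sided permutation test, p = 0.0002, the smallest possible with 10000 placements). Shares of all summits were lower than at random in introns (26.4% against 39.7%), intergenic sequence (11.1% against 28.1%), coding exons (3.02% against 13.9%) and 3' UTRs (0.959% against 4.47%, adjusted permutation p = 0.00028 for each). The shares sum to 100%, so the large promoter share lowers the others. This gives the lower share of introns, but not all of the lower shares of intergenic sequence, coding exons and 3' UTRs, as summits outside promoters show below. Those in 5' UTRs (0.612% against 0.789%, adjusted permutation p = 0.2) and other exons (1.71% against 1.59%, adjusted permutation p = 0.533) did not pass the threshold. Among the 2146 summits outside promoters, a comparison chosen after seeing the data, introns held more than at random (60.3% against 44.9%), as did other exons (3.91% against 1.80%), while intergenic sequence (25.3% against 31.7%), coding exons (6.90% against 15.7%) and 3' UTRs (2.19% against 5.05%) held less (adjusted permutation p = 0.00024 for each). The 5' UTRs were also higher there (1.40% against 0.892%, adjusted permutation p = 0.0006). Lower-ranked peaks, which overlapped no thresholded peak, had 11.7% of 126839 summits at promoters, close to random placement. The odds of a promoter position were 9.70 times higher for thresholded than for lower-ranked peaks (95% interval 9.14 to 10.3, Fisher's exact test, log10 of the p-value -1153).

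**Figure D2:**
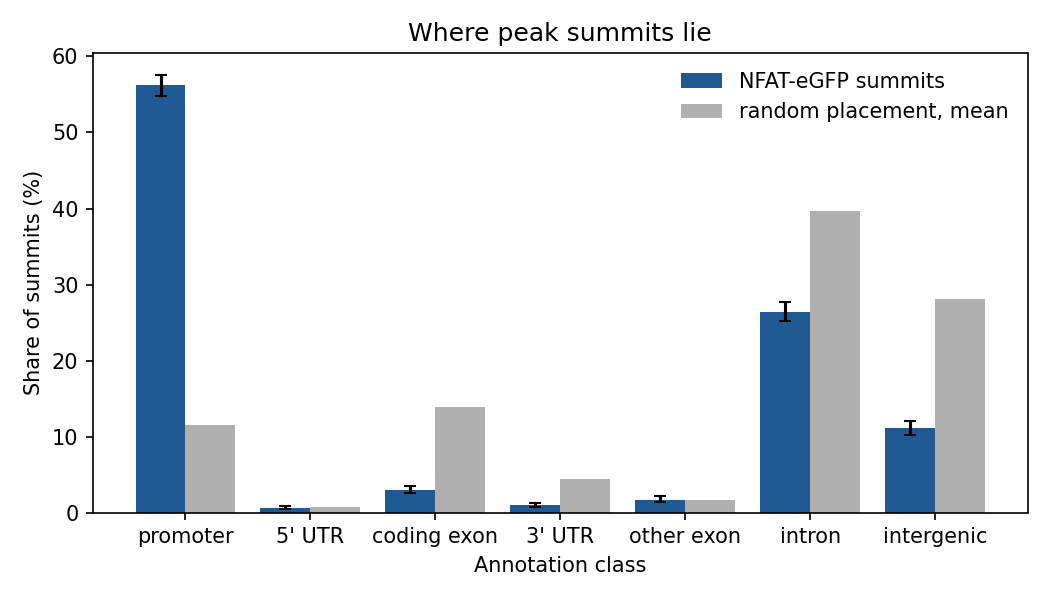
Share of the 4899 summits in each annotation class (blue, with Wilson 95% intervals) beside the mean of 10000 random placements (grey), in percent. Promoters hold 56.2% of summits against 11.5% at random.

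The promoter share rose with peak strength and was higher among peaks of the conservative list. Strength and membership of that list were not separated. Promoters held 66.0% of summits in the top quartile by signal, 63.1% in the second, 53.2% in the third and 42.5% in the lowest (Spearman rho = 0.179 across peaks, permutation p = 1e-05, the smallest possible, adjusted p = 0.0001). The 3660 peaks that overlapped the conservative list were at promoters in 58.7% of cases, and the 1239 found only in the larger list in 48.8% (odds ratio 1.49, Fisher's exact test, adjusted exact p = 9.25e-08). Peaks near ribosomal protein genes made up 1.97% of the former and 0.726% of the latter (odds ratio 2.74, adjusted exact p = 0.0226). The TATA box was also more common in peaks of the conservative list, at 12.8% against 7.91% (odds ratio 1.71, adjusted exact p = 4.97e-05), and the GAGA motif less common, at 1.91% against 4.28% (odds ratio 0.436, adjusted exact p = 0.000207). None of the other 44 comparisons of this family, over 25 motifs and 22 gene lists, had an adjusted p under 0.05.

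Summits carried sequence elements of housekeeping promoters and insulators more often than their flanks, and no excess of the NFAT core over flanks was found. The DNA replication-related element (DRE, TATCGATA), bound by Dref and BEAF-32, was within 50 bp of 3.25% of summits and in 0.612% of flank windows 400 bp away (5.30-fold, exact sign test, adjusted exact p = 2.72e-21). The CTCF-like core AGGTGGCGC was at 0.959% against 0.122% (7.83-fold, adjusted exact p = 2.91e-08) and the M1BP element GGTCACACT at 1.31% against 0.347% (3.76-fold, adjusted exact p = 7.87e-07). Smaller excesses were found for the Mad motif GGCGCC (3.55% against 2.06%, adjusted exact p = 6.3e-05), the E-box CAGCTG (6.35% against 5.0%, adjusted exact p = 0.0186) and the Sp1/KLF box GGGCGG (5.02% against 3.86%, adjusted exact p = 0.0229). The CA repeat was lower at summits (2.04% against 3.04%, adjusted exact p = 0.00922). The NFAT core GGAAA was at 26.4% of summits and 27.1% of flanks, a difference of -0.633 percentage points (95% interval -2.37 to 1.11, adjusted exact p = 0.681). The longer NFAT site TGGAAANWT was at 2.14% and 1.80% (difference 0.347 points, -0.206 to 0.900, adjusted exact p = 0.475). The 16 other motifs did not pass the threshold, among them the Rel/kappaB site (0.796% against 0.714%, adjusted exact p = 0.931), AP-1 (0.837% against 1.04%, adjusted exact p = 0.612), GAGA (2.51% against 2.49%, adjusted exact p = 1) and Zelda (0.429% against 0.551%, adjusted exact p = 0.679). In windows of 100 bp either side the NFAT core was lower at summits (difference -3.23 points, adjusted exact p = 0.00433). Against dinucleotide-shuffled sequence it was higher by 7.16 points at summits (95% interval 5.60 to 8.73) and by 4.57 points in flanks (2.97 to 6.17). The shuffled share was 19.3% at summits and 22.5% in flanks, so base composition differs between these windows. The excess over composition was larger at summits, and the difference between these excesses was not tested. The DRE and M1BP calls were lost at the 2018 summits over 500 bp from any TSS, the CAGCTG call in the conservative list (0.972 points) and replicate 1 alone (0.224 points), the Sp1/KLF call in the conservative list (0.844 points) and, with the direction turned, in replicate 1 alone (-0.268 points) and the stronger 50% of peaks (-0.735 points), and without a turn in replicate 2 alone (0.476 points), the CA repeat call without windows that hold simple repeats, and the Mad call in replicate 2 alone (0.901 points, adjusted exact p = 0.0627).

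**Figure D3:**
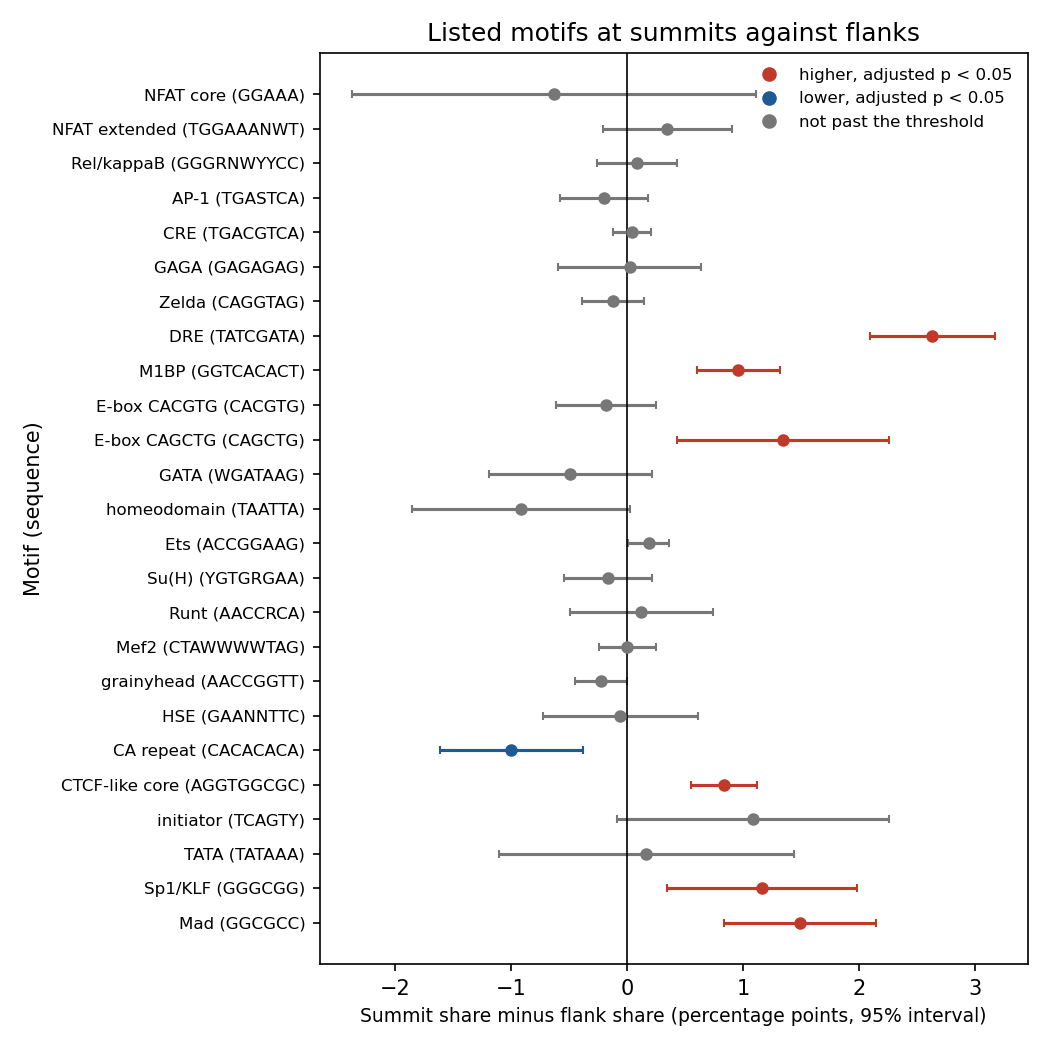
Difference between the share of summits and the share of flank windows with each of the 25 listed motifs, in percentage points with 95% intervals, for 4899 peaks. Red and blue points pass an adjusted p of 0.05 as higher or lower at summits. DRE stands furthest to the right at 2.63 points and the NFAT core lies at -0.633 with an interval that spans 0.

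Without a preset list, 206 of 2080 hexamers were higher at summits and 173 lower (exact sign tests, adjusted over all hexamers). The leading hexamers fell in a pair of families. CGATAG (9.33% of summits against 2.80% of flanks, adjusted exact p = 9.67e-41), TATCGA (10.9% against 4.33%, adjusted exact p = 1.57e-32) and ATCGAT (8.33% against 3.76%, adjusted exact p = 2.55e-19) are parts or near variants of the DRE, and all 8 hexamers that contain CGATA on either strand were higher. ACAGTG (11.1% against 4.27%, adjusted exact p = 2.28e-36) and ACACTG (10.3% against 4.0%, adjusted exact p = 3.12e-31) share the core CACTG or its reverse complement, and all 8 hexamers with it were higher. At the 2018 summits over 500 bp from any TSS, chosen for hexamers after seeing the data, ACAGTG had the lowest p (10.8% against 3.91%, adjusted exact p = 4.77e-14). The DRE was at 0.248% in both windows there. Over all 4899 peaks, CTCCTC had the smallest p of the hexamers that were lower at summits, at 2.69% against 6.18% (adjusted exact p = 1.29e-14). Of the 8 hexamers that contain GGAAA, none passed in either direction, and 2 had an unadjusted exact p under 0.05, AGGAAA (0.0151) and GGGAAA (0.0129), both lower at summits. With peak strength, Sp1/KLF fell from 6.86% in the lowest quartile to 3.10% in the top (rho = -0.0588, adjusted permutation p = 0.0002), while rho was above 0 for DRE (0.0424, adjusted permutation p = 0.0101), the CTCF-like core (0.0370, adjusted permutation p = 0.0238) and the longer NFAT site (1.39% in the lowest quartile and 2.45% in the top, rho = 0.0322, adjusted permutation p = 0.0411). From the top to the lowest quartile DRE was at 3.18%, 4.90%, 3.59% and 1.31% and the CTCF-like core at 1.55%, 0.735%, 1.06% and 0.490%. The longer NFAT site was at 2.45%, 2.69%, 2.04% and 1.39%, so none of these motifs rose steadily with strength. The CA repeat fell (rho = -0.0355, adjusted permutation p = 0.0257). The NFAT core did not pass (rho = 0.0249, adjusted permutation p = 0.114).

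Genes for protein synthesis, glycolysis and stress responses held NFAT-eGFP peaks more often than other genes. A summit lay within 1000 bp of a TSS in 3709 of 13968 protein-coding genes (26.6%). Expression was not measured here and no control immunoprecipitation was analysed. Whether recovery of active promoters in general gives the differences between gene lists, here and below, was therefore not tested. Cytoplasmic ribosomal protein genes reached 65 of 92 (70.7%, odds ratio 6.76, Fisher's exact test, adjusted exact p = 2.35e-17), with the strongest peaks at RpS27 (signal 700.0), RpL7 (606), RpL34b (475) and RpS21 (438), all within 81 bp of a TSS. Of the 12 glycolysis genes, 11 held a peak (odds ratio 30.5, adjusted exact p = 1.83e-05), led by Gapdh2 (540), Pgk (290.1), Eno (259) and Hex-A (227). Of 24 stress and heat shock genes, 17 did (odds ratio 6.74, adjusted exact p = 2.7e-05), led by the transcription factor Atf3 (498), the Sestrin gene Sesn (494), the small heat shock protein gene Hsp27 (411) and the translation repressor Thor (383). Chromatin and insulator genes (13 of 21, odds ratio 4.51, adjusted exact p = 0.00218) were led by ph-p (1319), Chro (777), brm (691) and E(z) (339). The housekeeping cytoskeleton and translation list (11 of 17, odds ratio 5.08, adjusted exact p = 0.00297) was led by Act5C (224), eEF1alpha1 (216), sqh (183) and alphaTub84B (180.5). Mitochondrial ribosomal protein genes passed with a smaller share (32 of 73, 43.8%, odds ratio 2.17, adjusted exact p = 0.00324), and their leading genes mRpL41 (1613), mRpS23 (1324), mRpS10 (1215.2) and mRpL23 (963) were at peaks of the top 25. The peaks at mRpS23 and mRpS10 are those assigned above to their neighbours CenG1A and Art3. Toll and Rel immune signalling also passed (10 of 18, odds ratio 3.46, adjusted exact p = 0.0273), with pll (342), Myd88 (243), cact (211) and Tak1 (206) as the strongest. That call was lost with the peaks of either replicate alone (odds ratio 1.62 in replicate 1 and 2.51 in replicate 2), and in replicate 1 alone the glycolysis (4.05, adjusted exact p = 0.066) and mitochondrial ribosomal (1.47, adjusted exact p = 0.319) calls were lost too. Over all alternatives, odds ratios ranged from 4.81 to 11.97 for stress and heat shock (the highest in replicate 2 alone), 2.83 to 8.66 for chromatin and insulator, 3.93 to 8.72 for the housekeeping list, 5.51 to 10.4 for ribosomal proteins and 1.47 to 3.94 for mitochondrial ribosomal proteins.

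Chemoreceptor and cuticle genes rarely held a thresholded peak, though 109 of 119 and 91 of 103 had a ranked one, against 86.7% of all genes. Odorant and gustatory receptor genes held a peak in 4 of 119 cases (3.36%, odds ratio 0.0952, adjusted exact p = 1.5e-10). The summits lay 744 bp from the TSS of Or88a, 922 bp from that of Gr89a, 856 bp from that of Gr64a and 733 bp from that of Gr32a. Those counted for Or88a, Gr64a and Gr32a were within 500 bp of the TSS of another gene, and that counted for Gr89a was in a coding exon. Genes found by the cuticle protein name pattern did so in 5 of 103 (odds ratio 0.140, adjusted exact p = 8.3e-08). The strongest of these 5 was at Cpr (208), which encodes cytochrome P450 reductase and not a cuticle protein, and the next were Ccp84Ad (62.4), TwdlN (61.8) and Cpr67B (59.5). Histone genes held a peak in 3 of 118 (odds ratio 0.0714, adjusted exact p = 2.96e-11), at the variants His2Av (199) and His3.3B (71.2) and at HisCl1 (108), a histamine-gated chloride channel caught by the name pattern. Only 17 of the 118 had even a ranked peak in the same window, and among genes with a ranked peak the histone result did not pass (odds ratio 0.485, adjusted exact p = 0.415). With replicate 1 or replicate 2 alone the odds ratio was 0.0475 or 0.0530 for receptors and 0.0550 or 0.0615 for cuticle genes.

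The remaining 12 lists did not pass the threshold. They include osmotic transport and calcineurin signalling, subjects linked to the NFAT family in other animals. Osmotic and ion transport genes held a peak in 12 of 34 cases (35.3%, adjusted exact p = 0.34), with the chloride channel gene Best1 (388), the kinase gene fray (248), Vha100-2 (192) and Nhe3 (181) as the strongest. Calcineurin and calcium signalling genes did so in 7 of 20 (35.0%, adjusted exact p = 0.546), with norpA (109.9), sra (106), SERCA (102) and Cam (78.5), and presynaptic genes in 5 of 32 (15.6%, adjusted exact p = 0.334), with Nrx-1 (124), Dap160 (98.8), Csp (85.8) and EndoA (68.1). JNK and AP-1 genes reached 7 of 13 (53.8%, adjusted exact p = 0.103), led by Mkk4 (518), msn (215), kay (141.5) and egr (96.5). The peak counted for msn lay 878 bp from its TSS and 38 bp from that of RpL8, for which it is also counted. Cell cycle genes reached 9 of 20 (adjusted exact p = 0.138), led by Cdk4 (198), E2f2 (166), geminin (124) and CycE (111), and Notch pathway genes 8 of 20 (adjusted exact p = 0.32), led by numb (225), mib1 (141), Su(H) (132) and mam (106). Blood and fat body genes reached 7 of 20 (adjusted exact p = 0.546; ush 213, LanB2 136, LanB1 115.5, Hml 96.7), and muscle and mesoderm genes 8 of 28 (adjusted exact p = 0.831; Msp300 430.0, tin 255, sls 151, mbc 121). Shares below the overall 26.6% that did not pass were found for Hox and segmentation genes (6 of 30, adjusted exact p = 0.621; Dll 284, en 77.6, hb 77.4, wg 71.4) and neural fate genes (3 of 26, adjusted exact p = 0.198; elav 495, insc 64.3, grh 63.8). Epidermis and trachea genes (4 of 20, adjusted exact p = 0.681) held peaks at dlg1 (200.4), crb (156), shg (132) and Ddc (91.7), and steroid hormone genes (4 of 19, adjusted exact p = 0.831) at E23 (401), Eip75B (119), usp (91.6) and ftz-f1 (67.0).

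**Figure D4:**
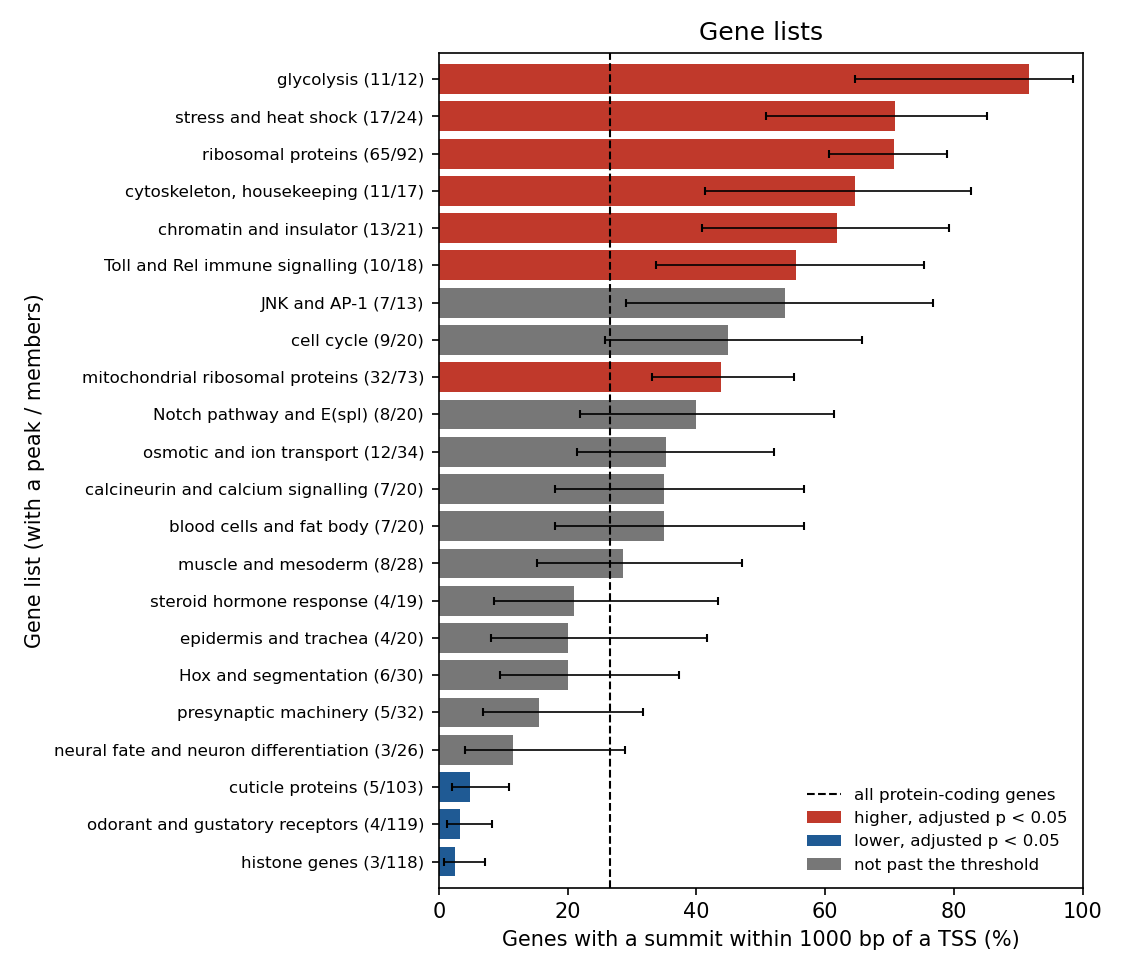
Share of each gene list with a summit within 1000 bp of a TSS, in percent, with Wilson 95% intervals and the counts beside each name. The dashed line is the 26.6% of all protein-coding genes, and bars in red or blue pass an adjusted p of 0.05 as higher or lower.

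The NFAT gene, the source of the tagged protein, held a cluster of peaks of its own. NFAT (FBgn0030505, X, 13624745 to 13664568) contained 11 thresholded peaks, and no further ones lay in the 5 kb on either side. The strongest (13640371 to 13640652, signal 1257) was the 10th strongest of the whole list and lay in an intron. A second intronic peak (13641105 to 13641318) had a signal of 544 and a peak near the 5' end (13626522 to 13626805) one of 278. Of the 11, 9 were intronic, 1 was in a coding exon and 1 was within 500 bp of a TSS, and 5 overlapped thresholded peaks in both replicates. The conservative list had 10 peaks there, replicate 1 had 8 and replicate 2 had 11. Windows of the same 49.8 kb across the large arms held a median of 1 peak, and 0.489% of them held 11 or more. The labels name transgenic flies but do not describe the construct. If it holds an inserted copy of the gene, signal at the native copy cannot be separated from signal at the inserted one.

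**Figure D5:**
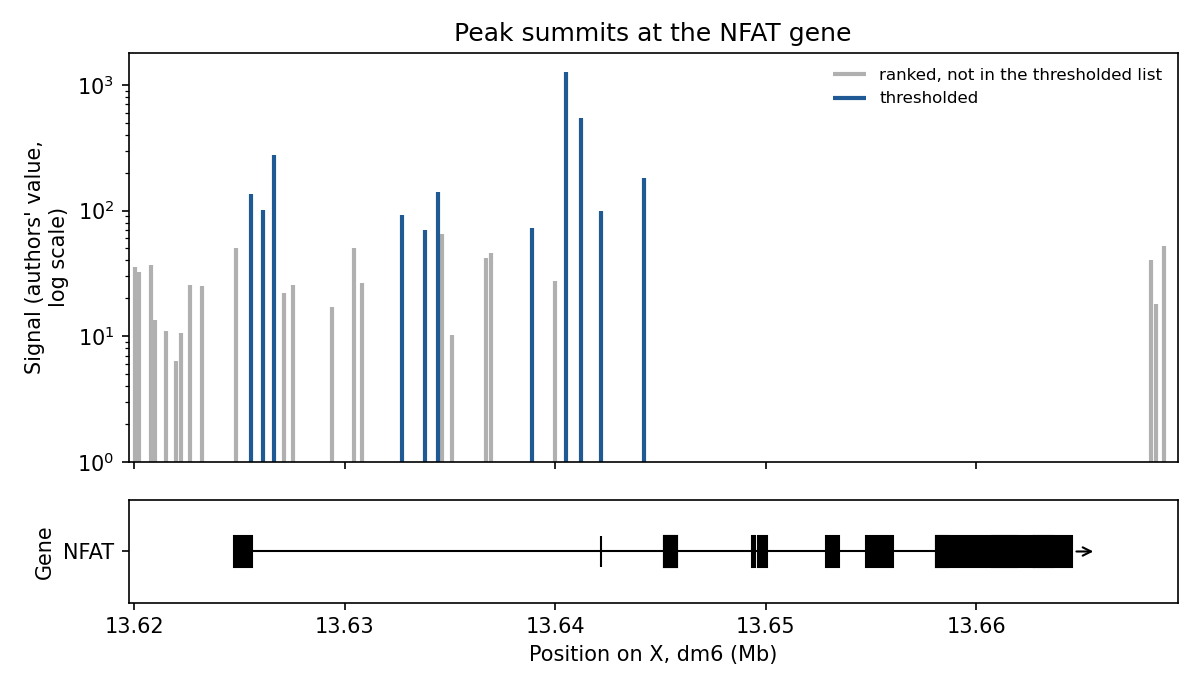
Summits of peaks at NFAT and 5 kb on either side on X, with signal on a log axis (upper) and the exons of the gene drawn to scale (lower, the arrow giving the direction of transcription). Blue lines are the 11 thresholded peaks, the tallest at 1257, and grey lines are ranked peaks outside the thresholded list.

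Peaks had similar densities on the large arms and were nearly missing from chromosome 4. Density ranged from 35.0 peaks per Mb on X and 35.9 on 3R to 38.7 on 2R. The lower density on X did not pass the threshold against all autosome arms (ratio of densities 0.949, exact binomial test, two-sided, p = 0.171) or against the 4 large ones alone (0.937, exact p = 0.0923, a comparison chosen after seeing the data). Chromosome 4 held 1 peak in 1.35 Mb, and Y held 4 in 3.67 Mb. Ranked peaks were few on chromosome 4 as well (31.2 per Mb, against 912 on 3L to 1083 on 3R). The shortage there is thus not particular to thresholded peaks.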

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

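The tests matched on GC content and distance for DRE, M1BP, the CTCF-like core and Mad, the split of the promoter-position test by motif, the promoter-sequence tests for CAGCTG and Sp1/KLF, the choice of the longer NFAT site for matching, the test and the empty stretch at the NFAT gene and the description of left-out peaks were chosen only after the results were seen. Signal also appears in ranked peaks that the main results leave out. On the arms, 177 peaks passed a global IDR of 0.01, the limit of the larger thresholded list, and are not in that list. The deposited descriptions name 1 more source item for the thresholded than for the ranked lists, and whether a filter removed these peaks or they are missing from the list for another reason was not tested. No control samples were analysed here. The strongest of the 177, with a signal of 1562, lay in an intron near cbt (2L, 480923 to 481248) and would rank 5th. The next were near Lk6 (3R, 11760901 to 11761178, signal 1332), larp (811), trx (519) and tara (475). Of the 177, 105 lay on 3R (59.3%, against 23.5% of thresholded peaks, Fisher's exact test, p = 2.64e-23). Joined at distances up to 20 kb they formed 81 groups, and the 36 groups of 2 or more peaks enclosed 1 thresholded peak in all. A gene near such a peak alone is counted in the report as without a peak.

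DRE, M1BP, the CTCF-like core, Mad, CAGCTG and Sp1/KLF were more common at summits than in flanks. Promoter sequence in general is argued against for the first 4 of these as a set, since 10.9% of thresholded and 4.62% of lower-ranked promoter summits held at least 1 (ratio 2.36, Fisher's exact test, p = 2.66e-33, or 1.75 with the latter weighted to the same distances, and 1.15 for Mad alone, p = 0.235), but it may account for CAGCTG (1.05, p = 0.54), while Sp1/KLF was less common at thresholded promoter summits (0.743, p = 0.00197) and had its excess at summits over 500 bp from any TSS (2.08 points), which promoter sequence would not give. Thresholded and lower-ranked promoter summits were also matched on GC content (median 43.6% against 50.5%) and distance from the TSS, in 10 and 5 groups. The odds ratios of DRE (2.21, 95% interval 1.75 to 2.78), the CTCF-like core (4.80) and Mad (2.02, 1.56 to 2.62) lay above 1. Differences in composition and distance between groups would not give this, and differences within a group were not matched. Position within promoters alone was to be argued against if at least 2 of the 4 motifs stayed more common at summits over 500 bp from any TSS. The CTCF-like core and Mad did, and DRE and M1BP did not (2 of 4). The flanks there were not matched on composition. Some G-rich sequence was higher at these summits, such as AGGGGG (8.13% against 3.87%), and A-rich sequence such as CAAAAA was lower (15.5% against 22.2%). Composition could add to both excesses, so this test does not decide. The matched values speak against distance between the groups as the only cause for DRE, the CTCF-like core and Mad. Position within a group was not matched and DRE had no excess at those summits, so finer position stays open, for DRE in particular. For M1BP the matched odds ratio was 1.34 (0.971 to 1.84) and the difference at those summits 0.198 points, so composition and distance cannot be told apart from other causes there. A general recovery of active promoters by the GFP immunoprecipitation stays open for DRE, M1BP and CAGCTG. It is not decided for the CTCF-like core, Mad and Sp1/KLF, since composition was not matched where their excess lay over 500 bp from any TSS. Recovery of active chromatin in general and any biological explanation were not tested.

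The NFAT core was not more common at summits than in flanks. An excess of the core over flanks of 5 points or more at the strongest peaks is argued against by the bound set beforehand, narrowly. In the top quartile its share exceeded the flank by 1.47 points (95% interval -1.94 to 4.88), and the bound was an upper limit under 5 points, so a smaller excess stays open. Over all peaks, shuffled sequence held the core less often at summits (19.3%) than in flanks (22.5%). An excess over composition therefore stays open too, and direct recognition is not decided. Whether promoter peaks hid the core was tested at summits over 500 bp from any TSS. There it was at 26.5% against 30.03% in flanks, a difference of -3.57 points (-6.33 to -0.801). This met the same bound for arguing against a hidden excess. Other A-rich sequence was also lower at these summits, such as CAAAAA (15.5% against 22.2%), and the flanks were not matched on composition. Composition could lower the core there, so the test does not decide whether promoter peaks hid it. The longer site TGGAAANWT was followed up because, of 25 motifs compared between thresholded and lower-ranked promoter summits, it was at 2.29% against 1.19% (Fisher's exact test, unadjusted p = 2.07e-05). Matched on GC content and distance, its odds ratio was 1.58 (1.15 to 2.17, Mantel-Haenszel chi-square test, p = 0.00476, 1 of 8 motifs matched in this way), but the core gave 0.987 (0.893 to 1.09, p = 0.796), so direct binding at a small share of promoters is a hypothesis, found and tested on the same data.

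Extra copies of the gene, if the transgene holds them, may have raised the 11 peaks at NFAT, or the protein may bind its own gene. Ranked peaks in the 5' part (13624745 to 13651294) had a median signal of 67.4 against 19.1 over X. In the 3' part (13651294 to 13664568) 0 ranked peaks were found where the density on X would give 13.1, within a stretch of 24.1 kb without one (13644206 to 13668298) that starts in the 5' part and ends past the gene. The ranked list of replicate 2 alone has 7 summits in that stretch, the conservative one 1 and that of replicate 1 has 0, 46 of 23268 gaps on X are at least as long, and it could not be told whether the stretch is truly without peaks or whether they are missing from the list. Extra copies of the whole gene would raise the 3' part as well, but the labels do not say which part of the gene the transgene holds. With no peaks there in the series-level list, the signal of the 3' part also has no value, so the explanations cannot be told apart.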

How the results depend on the processing

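The settings called added here were chosen after seeing the data. Of 64 comparisons of a main result with an alternative, 60 kept the direction and the side of the threshold, or stayed within 1.5 times for a count. The promoter share stayed above random placement in all 10 alternatives, from 48.7% (250 bp) to 66.0% (1000 bp), and 5 location classes differed in each of 4 other peak sets. Among summits outside promoters only (added) 6 classes differed: introns (60.3%) and 5' UTRs (1.40%) reversed and other exons (3.91%) passed, because shares of all summits fall where promoters rise. With 1 replicate alone, promoter shares were 60.8% to 61.6%, motifs past the threshold 5 to 8, hexamers 384 to 415, gene lists 7 to 10 and peaks at NFAT (added) 8 to 11. The peak count moved from 4924 to 2455 at a global IDR of 0.001 (added), by construction.

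Of 275 comparisons of single motifs, 14 lost and 14 gained a call and 5 reversed, and the cause was not tested except where given. Values are differences in percentage points. With 1 replicate alone, GAGA ranged from -1.16 (reversed) to 0.150, CACGTG from -0.894 to -0.300, CAGCTG from 0.224 to 1.43, TATA from 1.80 to 3.67, Sp1/KLF from -0.268 (reversed) to 0.476 (lost), and Mad from 0.901 to 1.48. The conservative list lost CAGCTG (0.972) and Sp1/KLF (0.844). The stronger 50% of peaks lost CAGCTG (0.817), gained TATA (3.47) and reversed Sp1/KLF (-0.735). With the left-out peaks added back (added) homeodomain was lower (-1.34), and without 82 peaks below their matched signals (added) the CA repeat was lost (-0.664). At the 2018 summits over 500 bp from any TSS, 4 listed motifs and 75 hexamers (added) passed instead of 7 and 379, with fewer peaks tested. DRE (0), M1BP (0.198), CAGCTG (0.793) and the CA repeat (-0.545) were lost there, and CACGTG was lower (-1.19). Windows of 25 bp gained the initiator (1.12) and lost Sp1/KLF (0.388). Windows of 100 bp gained GAGA (1.78), TATA (3.14) and a lower NFAT core (-3.23), and lost Sp1/KLF (0.469). Without simple repeats the CA repeat was lost (-0.471). Against dinucleotide shuffles 13 motifs passed. The NFAT core (7.16) and CA repeat (1.47) reversed, and the longer NFAT site (1.10), CRE (0.163), GAGA (1.57), initiator (2.59) and a lower CACGTG (-0.572) were gained. Flank sequence against its own shuffle gave 4.57 for the NFAT core and 2.43 for the CA repeat, so this background differs from genomic sequence at flanks too.

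Of 218 comparisons of single gene lists, 8 lost and 5 gained a call, and the cause was not tested. Toll and Rel signalling was lost in the stronger 50% of peaks (odds ratio 2.41), against genes with a ranked peak (2.84), by gene length (2.75) and with 1 replicate alone (1.62 to 2.51). With 1 replicate alone glycolysis ranged from 4.05 to 15.7, mitochondrial ribosomal proteins from 1.47 to 2.08 and JNK and AP-1 from 2.52 to 3.66, and JNK and AP-1 also passed with the left-out peaks (4.29, added). Histone genes were lost against genes with a ranked peak (0.485). The conservative list gained neural fate (0.136), gene bodies cell cycle (3.05), and gene length groups presynaptic machinery (0.304). For glycolysis, 2 alternatives gave no finite odds ratio. Depth is unknown and was not tested as the cause of the shorter list of replicate 1.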

Other observations

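The windows of dense peaks, the summit positions, the expected share for divergent pairs and the interval on chromosome 4 were chosen only after the results were seen. Peaks clustered at a few genes. The densest 50 kb window (3L, 8675815 to 8725814) held 23 peaks with a median signal of 73.9, and 13 of them had their nearest TSS at hry, the pair-rule gene hairy. Only 1 of the 23 overlapped thresholded peaks in both replicates, and 4 were at promoters. A window on X (7691686 to 7741685) held 17 peaks, 15 of them nearest to CHES-1-like, a forkhead gene, and 11 were in both replicates.

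Summits at promoters lay mostly just upstream. The median position was -48 bp from the nearest TSS, the middle 50% lay between -117 and 3 bp, and 2035 of 2753 (73.9%) were upstream (exact binomial test, two-sided, p = 3.89e-147).

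A hypothesis set before its test was that genes that share a promoter region with a divergent neighbour more often hold a peak. Of 3815 protein-coding genes with an opposite-strand TSS upstream within 500 bp, 45.5% had a summit within 1000 bp of a TSS, and of 10153 other genes 19.5% did (odds ratio 3.45, Fisher's exact test, p = 5.6e-199). For summits within 500 bp the odds ratio was 3.95. A peak between such a pair is counted for both genes. The p-value and the interval below treat these genes as independent, so both overstate the certainty. If each gene brought a peak independently and as often as the other genes do, 35.1% of these genes would have one, below the observed interval of 43.9 to 47.04%. The excess is consistent with a preference for divergent promoters, but expression level, which was not measured here, may differ between these genes and was not tested.

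Chromosome 4 was short of ranked peaks as well, with 42 on 0.956 Mb of sequence that is not repeat-masked, or 43.9 per Mb, 28.4-fold fewer than the 1246 per Mb of the large autosome arms. A test set beforehand would have argued against masked sequence as the cause at over 5-fold, and this was exceeded. Another asked whether the lists stop at the same signal everywhere, which would give chromosome 4 a lower median, and found 23.8 (bootstrap 95% interval 19.4 to 31.02) against 22.5, which decides nothing. Stretches of over 10 kb without a ranked peak made up 96.6% of chromosome 4, 75.5% of Y and 15.8% (3R) to 29.1% (3L) of the large arms.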
